A study of Callithrix jacchus with 4 samples.

How the data were processed

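RNA of frontal cortex from adult common marmosets was sequenced in 4 libraries, 2 labelled wild type and 2 labelled as carrying an APP transgene. Per the labels, total RNA was extracted with a column kit (RNeasy Mini) and libraries were made with KAPA Hyper reagents for Illumina sequencing. The strandedness of the libraries is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

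The authors deposited whole-number read counts per gene symbol, 1 column per library, with no normalization. The submitters' processing notes name STAR 2.5.3a, featureCounts 1.5.2 and kallisto 0.46.2, without their roles. The genome build and annotation are not given in the sources used here, and no coordinates are printed. The table held 35108 genes, of which 8054 had no count in any library and 17624 had an identifier of the LOC form in place of a symbol. No column and no row without a gene name was left out. Total counts ranged from 12657323 to 18932180. A count of 3 corresponds to 0.17 to 0.23 CPM, and lower levels cannot be told from 0. Every pair of libraries differed by more than sampling noise (chi-square per degree of freedom of 8.0 to 53.4 over genes), which shows that no library repeats the counts of another but not that each came from its own animal. Each library was counted as 1 sample, as labelled.

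Counts were analysed in R 4.3.3. The design, the gene lists, the rule for named genes and the alternatives were set before the data were examined, except where stated. Genes were kept with edgeR's filterByExpr (16385 genes), and library sizes were scaled by TMM. The main test was the quasi-likelihood F-test of edgeR 4.0.16 with genotype as the only term, which leaves 2 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg over all genes kept, with a threshold of 0.05. The biological coefficient of variation was 24.5%. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.33, so none is reported. Values in CPM use the TMM-scaled library sizes. The log2 fold changes are those of the edgeR fit with their standard errors.

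The 32 gene lists covered APP processing, Alzheimer's risk, glial states, synapses, metabolism, stress responses and cortical cell types, and 29 had at least 5 genes kept. Blood markers (2 genes kept), choroid plexus and ependymal markers (4 genes kept) and mitochondrially encoded genes (0 matched) were not tested. Of 718 entries, 657 matched the table by symbol and 8 HLA entries were matched to the CAJA- symbols of marmoset MHC genes, a step decided after the table's names were seen. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, again with the correlation estimated from the data, where camera also uses the 2 residual degrees of freedom of the fit, and with fry. Camera asks whether a list moves relative to other genes, and fry whether its genes move on balance in 1 direction.

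The rule for named genes took APP, EEF1A1 and a fixed set always, the genes with the largest fitted change among those past the threshold, and the 3 members with the smallest p of each called list and of 5 fixed lists. Since no gene passed, its fallback applied: the 6 genes per direction with the smallest p, a mean count of at least 20 and no overlap between the groups. The rule asked for genes with a symbol, and identifiers of the LOC form were not taken as symbols, a reading settled after the table was seen. The results of 3 genes that met the rule are not reported here, and no others were put in their place. Other genes are said to have been chosen after their values were seen.

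The alternatives were DESeq2 1.42.0, limma-voom, DESeq2-type (RLE) scaling, library totals without scaling, no filter on low counts, a minimum mean count of 50, a test against a fold of 1.2, the replicate number as a block, leaving out each library in turn, and leaving out 534 genes assigned to X or Y. That assignment came by symbol from another marmoset assembly, calJac240_pri, which need not be the build behind the counts. Where leaving out a library left a group with 1 sample, that sample was assumed to vary like those of the other group. A block with the replicate numbers crossed and limma-voom with library weights were added after seeing the data.

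The steps were tested on simulated data: 10 sets of 16385 genes with the means, dispersions and library sizes of the real libraries and 200 genes changed between transgenic and wild type. For this comparison edgeR recovered 24.4% of genes changed 2-fold, 77.8% of those changed 4-fold, 93.2% at 8-fold and 97.6% at 16-fold. DESeq2 recovered 41.8%, 84.0%, 91.6% and 95.0%. No simulated library stood apart as transgenic library 2 did, so these shares need not hold for the real libraries. In the real data TVP23B, fitted as 20.1-fold lower, did not pass edgeR's test (adjusted p = 0.47). On average edgeR called 24.1 unchanged genes per set and DESeq2 49.9, so more of their calls were false than the threshold allows for. Camera with the preset correlation called 10 of 10 lists of 20 independent genes raised 2-fold and 0 of 200 unchanged lists, and simulated genes within a list were not correlated.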

Results

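Gene expression was measured by RNA sequencing of frontal cortex from adult common marmosets (Callithrix jacchus), a small New World monkey. The series held 4 libraries, 2 from wild-type animals and 2 from animals carrying a mutant APP transgene under the human EF1α promoter. APP encodes the amyloid precursor protein, from which the amyloid-β peptide of Alzheimer's disease is cut. The comparison asks how the cortical transcriptome of the transgenic animals differed from that of the wild type. The counts summed to 12657323 and 13569838 in wild-type libraries 1 and 2, and to 13462167 and 18932180 in transgenic libraries 1 and 2. The labels give the sex of the transgenic animals as female and none for the wild type. They do not say in words that the libraries of a group came from separate animals. The Y-linked gene KDM5D had 2 and 243 counts in wild-type libraries 1 and 2, so the wild-type pair came from different animals. It had 0 in both transgenic libraries, so sex is confounded with genotype in part. The spread between the transgenic libraries may be technical.

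APP itself was at 1822 and 2182 CPM (counts scaled to library size) in the wild-type libraries and at 2143 and 2748 in the transgenic libraries. Transgenic library 1 lay between the wild-type libraries and transgenic library 2 above both. The fitted fold change was 1.22 (log2 0.29 ± 0.22 SE, n = 2 per group). In edgeR's quasi-likelihood test the p was 0.24 unadjusted and 0.80 adjusted over all genes. The difference could not be told from the spread between libraries. Without transgenic library 2 the log2 fold change was 0.09, and without transgenic library 1 it was 0.46. The annotation and the sequence of the transgene were not used here, so it is open whether transgene reads were counted on the marmoset gene. EEF1A1, the marmoset gene for the translation elongation factor whose human promoter drives the transgene, had a log2 fold change of 0.31 ± 0.22 (adjusted p = 0.80), which was 0.057 without transgenic library 2 and 0.53 without transgenic library 1, where it passed (adjusted p = 0.037). Of the 23 genes of APP processing, 14 were higher and 9 lower in sign, with a median log2 fold change of 0.03 (-0.019 without wild-type library 1), and the list was not called (adjusted p = 0.70 in the camera gene set test). The β-secretase gene BACE1 was at 174 ± 9.0 CPM (mean ± SD, n = 2) in wild type and 199 ± 25.1 in transgenic cortex. The APP adaptor APBA1 was at 177 ± 19.4 and 230 ± 18.6 CPM, the insulin-degrading enzyme gene IDE at 28.8 ± 3.1 and 23.5 ± 0.2 CPM, and the γ-secretase subunit gene NCSTN at 58.3 ± 2.6 and 67.9 ± 5.0 CPM. The adjusted p of these genes lay between 0.79 and 0.80. MAPT, the gene for tau, was at 609 ± 10.5 and 720 ± 104 CPM (adjusted p = 0.79).

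No single gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test among the 16385 genes tested. The smallest adjusted p was 0.075. At an unadjusted p under 0.05 there were 921 genes, 530 higher and 391 lower in transgenic cortex, where 819 were expected by chance. DESeq2 called 46 genes, 25 higher and 21 lower, and limma-voom called 0. Without transgenic library 2, edgeR called 3 genes, and without transgenic library 1 it called 1710. The genes named next have the smallest p in each direction among genes with a symbol, a mean count of at least 20 and no overlap between the groups. They do not pass in edgeR, although DESeq2 called all 11.

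Among the 6 genes named on the higher side were genes for a neuropeptide and for cell adhesion proteins. PDYN, the precursor of the dynorphin opioid peptides, was at 18.3 and 19.5 CPM in wild type and at 63.4 and 103 CPM in transgenic cortex, a fitted 4.40-fold (log2 2.14 ± 0.27 SE, n = 2 per group; adjusted p = 0.73 in edgeR and 2.99e-09 in DESeq2). C2CD4C was at 15.0 ± 0.4 CPM (mean ± SD, n = 2) in wild type and 42.2 ± 2.5 in transgenic cortex. PCDH19, a protocadherin, was at 31.3 ± 4.4 and 61.5 ± 1.5 CPM. The teneurin gene TENM3 was at 94.0 ± 1.9 and 152 ± 4.7 CPM, NUP50, which encodes a nuclear pore protein, at 118 ± 9.2 and 209 ± 19.4 CPM, and SHISAL1 at 69.01 ± 4.6 and 115 ± 2.5 CPM.

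On the lower side, 2 of the 5 genes named encode subunits of voltage-gated channels. SCN4B, a sodium channel β subunit, was at 70.4 ± 26.5 CPM in wild type and 22.4 ± 3.6 in transgenic cortex (log2 fold change -1.65 ± 0.30 SE, n = 2 per group; adjusted p = 0.79 in edgeR and 0.00057 in DESeq2). The potassium channel subunit gene KCNS1 was at 243 ± 16.7 and 146 ± 5.2 CPM. PANX2, a pannexin, was at 111 ± 10.3 and 58.2 ± 9.1 CPM. TYROBP, the signalling partner of the microglial receptor TREM2, was at 17.3 ± 3.2 and 6.8 ± 0.8 CPM. TVP23B had 47 and 58 counts in the wild-type libraries and 2 and 4 in the transgenic libraries.

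**Figure D1:**
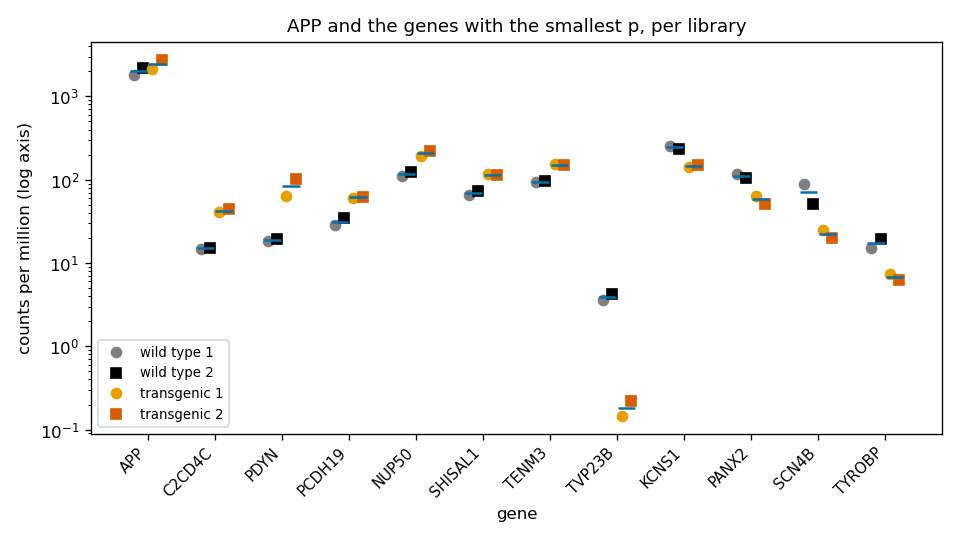
CPM on a log axis for APP and for the genes named by smallest p, 6 higher and 5 lower in transgenic cortex. Each library is 1 point and a blue line marks each group's mean. The ranking by p was among genes with a symbol, a mean count of at least 20 and no overlap between the groups. In the 11 genes other than APP both transgenic libraries lie on the same side of both wild-type libraries, as the rule for naming them required, whereas APP in transgenic library 1 (2143) lies between the wild-type libraries (1822 and 2182).

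Of 29 gene lists tested with camera at a preset inter-gene correlation of 0.01, 11 were called at an adjusted p of at most 0.05, 6 as higher and 5 as lower in transgenic cortex. None of these calls held when the correlation between genes was estimated from the data: adjusted p = 0.85 with an estimated correlation for each of the 11 lists. Camera then also uses the 2 residual degrees of freedom of the fit, and with these at the preset correlation, a setting chosen after the data were seen, it called 0 lists. The rotation test fry called 0 lists in its directional form. In the form of fry that ignores direction, deep cortical layer genes alone passed (adjusted p = 0.036). Camera with the preset correlation did not call that list (adjusted p = 0.089). No member of any list passed edgeR's test adjusted over all genes.

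Microglial genes were lower in both transgenic libraries. Of 14 markers, 13 were lower in sign, with a median log2 fold change of -0.75 (camera adjusted p = 0.00020; adjusted p = 0.85 with an estimated correlation). The median deviation from the wild-type mean was -0.70 in transgenic library 1 and -0.98 in transgenic library 2, against -0.22 and 0.22 in the wild-type libraries. In 6 of the 14 genes both transgenic libraries lay below both wild-type libraries. For 1 gene chance gives 16.7% in each direction, but genes measured in the same libraries are not independent, so the count is no test. TYROBP was the 1 gene called when adjusted over the list alone. C1QA, a chain of the complement component that starts the classical pathway, was at 31.3 ± 4.7 CPM (mean ± SD, n = 2) in wild type and 12.2 ± 6.1 in transgenic cortex. LY86 was at 6.7 ± 2.6 and 2.9 ± 0.0 CPM and AIF1, the gene for the microglial marker IBA1, at 10.9 ± 0.8 and 6.8 ± 1.6 CPM. The call held without each library in turn. PTPRC, the gene for the leukocyte antigen CD45, was the exception in sign, at 8.1 and 7.4 CPM in wild type and 4.9 and 25.4 in transgenic libraries 1 and 2.

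The disease-associated microglia genes, a set named for cells around amyloid plaques in mouse models, were not called (adjusted p = 0.22, median log2 fold change -0.07, 8 of 20 higher in sign). Without transgenic library 2 they were called as lower (adjusted p = 0.015, median -0.16), and without transgenic library 1 the median was 0.044. TREM2 was at 15.7 ± 7.8 CPM in wild type and 9.0 ± 0.3 in transgenic cortex, and APOE, the lipid carrier whose variants set Alzheimer's risk, at 612 ± 8.0 and 466 ± 74.2 CPM. CTSZ was at 27.0 ± 2.4 and 17.3 ± 2.4 CPM and LGALS3 at 16.6 ± 1.5 and 25.8 ± 5.5 CPM. TYROBP was again the 1 member called when adjusted over the list alone. The Alzheimer risk loci had a median log2 fold change of 0.00 over 24 genes and were not called (adjusted p = 0.85).

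Genes of oxidative phosphorylation encoded in the nucleus were slightly lower in both transgenic libraries. Of 50 genes, 45 were lower in sign and 33 had both transgenic libraries below both wild-type libraries, with a median log2 fold change of -0.19 (camera adjusted p = 0.00020; adjusted p = 0.85 with an estimated correlation). The ATP synthase subunit gene ATP5F1D was at 66.0 ± 9.6 CPM in wild type and 44.95 ± 4.6 in transgenic cortex, ATP5PF at 88.8 ± 12.2 and 65.1 ± 3.9 CPM, and SDHB, a subunit of complex II, at 68.4 ± 6.6 and 52.3 ± 0.6 CPM. The call ended without wild-type library 1 (adjusted p = 0.11, median -0.10) and without transgenic library 1 (adjusted p = 0.064, median -0.16).

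Endothelial markers were lower in 8 of 10 genes, with a median log2 fold change of -0.65 (camera adjusted p = 0.0069; adjusted p = 0.85 with an estimated correlation). The tight junction gene CLDN5 was at 37.9 ± 6.0 CPM in wild type and 24.6 ± 5.5 in transgenic cortex, ESAM at 25.8 ± 1.1 and 13.7 ± 3.4 CPM, and the VEGF receptor gene FLT1 at 79.1 ± 23.6 and 37.0 ± 25.4 CPM. The call ended without wild-type library 1 (adjusted p = 0.11, median -0.28) and without transgenic library 1, where the median grew to -0.88 (adjusted p = 0.064).

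Genes of antigen presentation had the smallest camera p. Of 16 genes 15 were higher in sign, with a median log2 fold change of 1.37 (adjusted p = 5.39e-07; adjusted p = 0.85 with an estimated correlation), and 3 were called when adjusted over the list alone. CD74, the invariant chain of MHC class II, was at 8.9 and 11.04 CPM in wild type and 23.0 and 31.3 CPM in transgenic cortex (log2 1.44 ± 0.25 SE, n = 2 per group; adjusted p = 0.79 in edgeR and 0.0051 in DESeq2). The class II α chain gene CAJA-DRA was at 2.5 and 3.7 CPM in wild type and 8.3 and 18.1 CPM in transgenic cortex, and CAJA-DPA1 had 2 and 3 counts against 18 and 22. CAJA- is the prefix of marmoset MHC genes, which are polymorphic and alike in sequence, so reads can be split among them. The list's median was carried by transgenic library 2: it was 1.76 above the wild-type mean there and 0.17 in transgenic library 1. Without transgenic library 2 the median log2 fold change was 0.15 and the list was still called (adjusted p = 0.018).

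Interferon response genes were higher in transgenic library 2 and near wild type in transgenic library 1. The median deviation was 1.53 in library 2 and -0.01 in library 1, and 13 of 17 genes were higher in sign over both (median log2 fold change 0.98, camera adjusted p = 0.024; adjusted p = 0.85 with an estimated correlation). The antiviral GTPase gene MX1 was at 42.9 ± 4.8 CPM in wild type and at 60.7 and 123 CPM in the transgenic libraries. IFIT2 was at 52.1 ± 0.7 CPM in wild type and at 67.4 and 346 CPM, and MX2 at 2.6 ± 1.0 CPM and at 4.7 and 13.2 CPM. Without transgenic library 2 the call was lost (adjusted p = 0.92, median log2 fold change -0.05), and without transgenic library 1 the median was 1.60.

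Astrocyte and oligodendrocyte markers were lower in transgenic library 2 and near the wild type in transgenic library 1. Over 12 astrocyte markers the median deviation was -1.93 in transgenic library 2 and -0.01 in transgenic library 1 (median log2 fold change -0.59, camera adjusted p = 0.0069; adjusted p = 0.85 with an estimated correlation). Over 12 oligodendrocyte markers the medians were -1.23 and 0.06 (median log2 fold change -0.43, camera adjusted p = 0.037; adjusted p = 0.85 with an estimated correlation). Both calls were lost without transgenic library 2 (adjusted p = 0.92 and 0.20, medians -0.019 and 0.041) and without wild-type library 1 (adjusted p = 0.0998 and 0.43, medians -0.53 and -0.20), and the oligodendrocyte call was also lost with library totals without scaling (adjusted p = 0.070). Without transgenic library 1 the medians were -1.94 and -1.26. The astrocyte genes ALDH1L1 and S100B were at 123 and 121 CPM on average in wild type, at 97.8 and 77.1 CPM in transgenic library 1, and at 41.2 and 23.6 CPM in transgenic library 2. ALDOC was at 619 ± 126 CPM in wild type and 447 ± 58.1 in transgenic cortex. The myelin genes MBP, ERMN and OPALIN were at 914, 131 and 82.3 CPM on average in wild type, at 851, 126 and 71.3 CPM in transgenic library 1, and at 353, 34.9 and 30.6 CPM in transgenic library 2. GFAP, the intermediate filament of astrocytes, was at 606 ± 126 CPM in wild type and 696 ± 86.8 in transgenic cortex (adjusted p = 0.83).

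Reactive astrocyte genes were called as higher (11 of 14 in sign, median log2 fold change 0.64, camera adjusted p = 0.00042; adjusted p = 0.85 with an estimated correlation). The median deviation was 0.46 in transgenic library 1 and 0.90 in transgenic library 2, against -0.27 and 0.27 in the wild-type libraries, and the call held without each library in turn, with a median of 0.40 without transgenic library 2. OSMR, the oncostatin M receptor gene, was at 1.1 ± 0.0 CPM in wild type and at 3.1 and 9.4 CPM in the transgenic libraries. EMP1 was at 4.2 and 7.6 CPM in wild type and at 15.5 and 67.0 CPM, and the hyaluronan receptor gene CD44 at 2.2 ± 0.0 CPM and at 4.6 and 17.3 CPM.

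**Figure D2:**
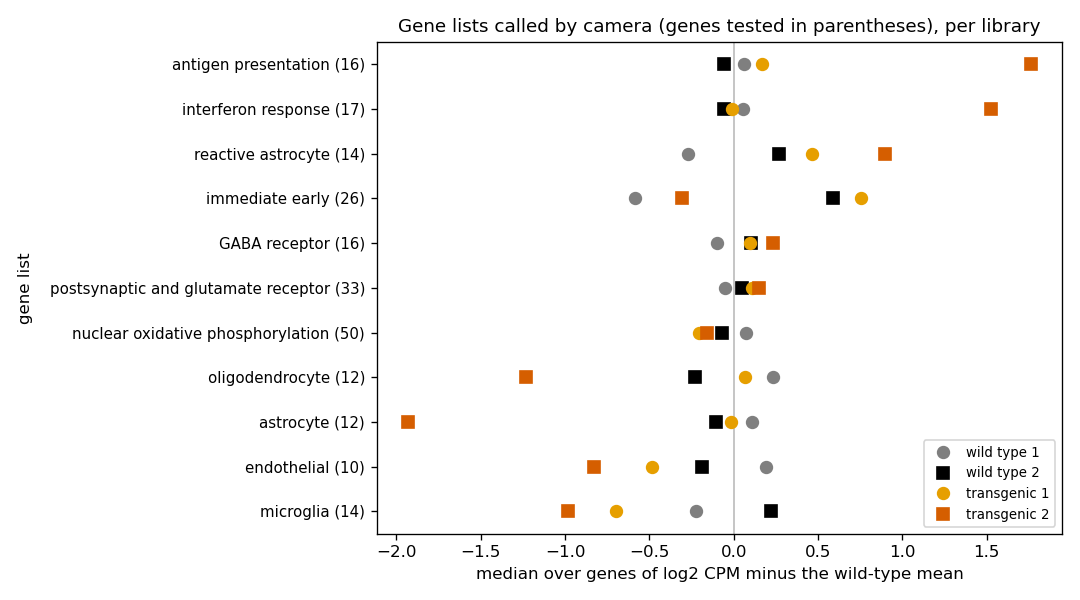
Median over the genes of each called list of the log2 CPM minus the wild-type mean, with 1 point per library. Transgenic library 2 lies apart in antigen presentation (1.76), interferon response (1.53), astrocyte (-1.93) and oligodendrocyte genes (-1.23), whereas in microglial genes both transgenic libraries (-0.70 and -0.98) lie below both wild-type libraries.

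Among neuronal lists, the postsynaptic and glutamate receptor genes were called as higher (25 of 33 in sign, median log2 fold change 0.14, camera adjusted p = 0.0079; adjusted p = 0.85 with an estimated correlation). DLGAP2, a postsynaptic scaffold gene, was at 39.1 ± 5.2 CPM in wild type and 62.6 ± 0.3 in transgenic cortex, and the AMPA receptor gene GRIA1 at 189 ± 5.6 and 277 ± 68.1 CPM. This call ended without wild-type library 1 (adjusted p = 0.40, median 0.10) and without transgenic library 2 (adjusted p = 0.053, median 0.11), and the median was 0.22 without wild-type library 2. GABA receptor genes were also called as higher (12 of 16 in sign, median 0.16, camera adjusted p = 0.040; adjusted p = 0.85 with an estimated correlation), with GABRA5 at 85.6 ± 2.3 and 143 ± 44.99 CPM, GABRG1 at 57.9 ± 4.9 and 75.1 ± 10.8 CPM and GABBR1 at 546 ± 35.8 and 676 ± 81.5 CPM. Among the 4 fits that left out a library, that call held only without wild-type library 2 (median 0.29), and it was also lost with no low-count filter (adjusted p = 0.054), without genes assigned to X or Y (adjusted p = 0.061) and with the replicate numbers crossed as a block, chosen after the data were seen (adjusted p = 0.070). The median was 0.046 without wild-type library 1, 0.23 without transgenic library 1 and 0.087 without transgenic library 2. Markers of excitatory neurons (median 0.07, adjusted p = 0.70) and inhibitory neurons (median 0.11, adjusted p = 0.31) and presynaptic genes (median 0.18, adjusted p = 0.14) were not called. The synaptic genes SYP and DLG4 were at 1223 ± 152 and 637 ± 41.2 CPM in wild type and at 1379 ± 119 and 707 ± 46.2 CPM in transgenic cortex.

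Immediate early genes, which neurons induce within minutes of activity, were called as higher over both libraries (19 of 26 in sign, median log2 fold change 0.30, camera adjusted p = 0.037; adjusted p = 0.85 with an estimated correlation). The libraries did not divide by genotype: the median deviation was -0.59 and 0.59 in wild-type libraries 1 and 2 and 0.75 and -0.31 in transgenic libraries 1 and 2. FOSB was at 25.4 ± 5.0 CPM in wild type and 40.5 ± 3.1 in transgenic cortex. ATF3 and GADD45B, stress-induced genes, were at 0.8 ± 0.7 and 21.0 ± 1.2 CPM in wild type, at 2.0 and 24.3 CPM in transgenic library 1 and at 21.7 and 133 CPM in transgenic library 2. The call was lost without wild-type library 1 (median -0.12, adjusted p = 0.45) and without transgenic library 1 (median -0.36, adjusted p = 0.83), and the median was 0.93 without wild-type library 2 and 0.62 without transgenic library 2.

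Transgenic library 2 stood apart from the other 3 libraries over the whole transcriptome. The first principal component held 63.1% of the variance and placed it at 69.4, with the others between -28.3 and -17.4. Of 14887 genes with a mean count of at least 20, 437 differed by more than 2-fold between the wild-type libraries and 362 between wild-type library 2 and transgenic library 1, against 1440 between the transgenic libraries.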

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

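The crossed block, the library weights, camera with the preset correlation and 2 degrees of freedom, and no other setting here were chosen after the data were seen. The count of 0 genes stayed 0 with limma-voom, both other scalings, the stricter filter, the 1.2-fold test, without genes assigned to X or Y, and with library weights. It was 46 with DESeq2, 5 with no low-count filter and between 0 and 1710 when a library was left out. The cause was not tested for DESeq2, which calls more unchanged genes in simulation. The 1710 genes came without transgenic library 1, where the spread rests on the wild-type pair alone, and 45 of the 46 DESeq2 genes were among them. The count of 11 gene lists was 18 with DESeq2, between 4 (without wild-type library 1) and 13 when a library was left out, and 0 with an estimated correlation or with fry. With an estimated correlation camera also uses the 2 residual degrees of freedom, and with these at the preset correlation it called 0 lists (smallest adjusted p = 0.36), so the degrees of freedom were enough to end the calls. For microglia the estimated correlation was -0.00022, below the preset 0.01, and the unadjusted camera p went from 2.07e-05 to 0.045. In every other called list the estimate was above the preset, from 0.090 (endothelial) to 0.88 (oligodendrocyte). For antigen presentation (estimate 0.58) the unadjusted camera p at 2 degrees of freedom was 0.030 with the preset and 0.19 with the estimate. The cause was not tested for fry. With the replicate number as a block, 0 genes and 12 lists were called. Same-numbered libraries did not deviate together (correlation of deviations across genes -0.14). With 2 libraries per group this compares 1 difference with 1 other, so it cannot exclude a pairing or a shared batch, and the labels state none. The block changed no call of a named gene or of the 13 lists counted below. With the crossed block 0 genes and 10 lists were called.

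Of 780 alternatives for 56 named genes, 731 kept direction and side of the threshold, 49 came to pass it and 0 reversed. No named gene passed in the main fit, so a kept side meant not passing. Most named genes had no overlap between the groups, so leaving out a library could hardly reverse them. Those that came to pass did so mostly with DESeq2 or without transgenic library 1. Of 208 for 13 lists, 151 kept both, 49 lost the call, 1 (disease-associated microglia, without transgenic library 2) gained it and 7 reversed, in the sign of the median or in the direction given by the list test. When a library was left out, the disease-associated microglia median ranged from -0.16 to 0.044 (log2 fold change), the immediate early median from -0.36 to 0.93, the interferon response median from -0.053 to 1.60, the oligodendrocyte median from -1.26 to 0.041 and the APP processing median from -0.019 to 0.10, and the last was -0.017 with library totals without scaling; the cause was not tested. Calls were kept but medians differed with limma-voom and with the replicate block for interferon response genes (0.48 and 0.59 against 0.98) and astrocyte genes (-0.98 and -0.96 against -0.59). Other than by leaving out a library or by another list test, the calls lost were those of GABA receptor genes (no low-count filter, no genes assigned to X or Y, crossed block) and oligodendrocyte genes (library totals). At a count of 3 or less, levels could not be told from 0 at these depths.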

Other observations

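The tests of astrocyte share, white blood cells, MHC alleles, more microglia, PVALB interneurons and place in the cortex, the count of meningeal genes and the other divisions of the libraries, were chosen after the result was seen, and genes outside the fixed lists and rules were chosen after their values were seen.

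Transgenic library 2 held a set of cytokine, chemokine and acute inflammatory transcripts that were near 0 in the other 3 libraries. CXCL10, an interferon-induced chemokine, had 3, 3 and 4 counts in wild-type libraries 1 and 2 and transgenic library 1, and 2551 in transgenic library 2. CXCL11 went from at most 1 count to 1861, CCL2 from at most 5 to 1322, IL6 from at most 1 to 320, and CSF3, the gene for granulocyte colony-stimulating factor, from 0 to 554. The interleukin-1 decoy receptor gene IL1R2 had 0, 0, 2 and 660 counts and the calprotectin gene S100A9 had 10, 8, 3 and 3705. The adhesion gene ICAM1 was at 0.7, 0.5, 1.3 and 93.3 CPM, and the transcription factor gene IRF1 at 3.1, 3.2, 3.5 and 111 CPM. Over the 18 tested genes of complement and inflammatory cytokines the median deviation was 1.11 in transgenic library 2 and -0.39 in transgenic library 1, and the list was not called over both (adjusted p = 0.14 in camera). Some glial genes went the other way in this library. TMEM119 had 112, 206 and 91 counts in the others and 3 here, and CX3CR1 had 485, 936 and 548 against 68. The astrocyte connexin gene GJB6 had 452, 399 and 407 against 34. These genes were picked from the low end. Of 14 microglial markers, 7 were over 2-fold below the wild-type mean here and 1 over 2-fold above it, and of 12 astrocyte markers 9 and 0.

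Other genes divided the libraries along lines of their own. Genes of meningeal fibroblasts were high in wild-type library 2 and transgenic library 1: SLC6A13 was at 54.6 and 59.5 CPM there and at 3.5 and 3.6 CPM in wild-type library 1 and transgenic library 2, and PRG4 at 24.2 and 57.9 against 2.7 and 2.6 CPM. Of 12 such genes, 4 of which had been used to see the division, 10 followed it and 9 by at least 2-fold. Some genes were several-fold higher in both transgenic libraries than in either wild-type library. LOC100407025 had 1 and 1 counts in wild type and 187 and 203 in transgenic cortex, LOC103789478 had 15 and 17 against 326 and 373, and ZWINT, a kinetochore gene, had 16 and 3 against 161 and 111. CARTPT, a neuropeptide gene of the upper cortical layers, was at 1.1 and 0.5 CPM in wild type and 3.6 and 11.4 CPM in transgenic cortex, and was the 1 of 8 upper layer genes called in edgeR when adjusted over the list alone. Its list was not called (adjusted p = 0.22 in camera).

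The 4 libraries can be divided into 2 pairs in 3 ways, too few for a share of divisions under 0.05. With the genotypes, 76 of 14887 genes lay fully apart by at least 2-fold and DESeq2 called 46. With wild-type library 1 and transgenic library 2 against the other pair, 94 genes lay apart and DESeq2 called 67, the highest of the other divisions. With the remaining division 20 lay apart and DESeq2 called 4. The calls of edgeR were 0 with the genotypes, and 1 and 0 with the other divisions. Of the 76 genes, 31 had an identifier of the LOC form, against 9 of the 94 and 7 of the 20.

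A candidate explanation for the state of transgenic library 2 is inflammation in that animal or piece of tissue. For the greater depth of this library, the median interferon response was 1.52 above the wild-type mean after thinning to the smallest total and 1.53 before. Thinning keeps each gene's expected share of the counts, so this median could hardly have moved, and the result decides nothing. A lower share of astrocytes was argued against only as the whole account, since the markers spread from a 15.9-fold lower GJB6 to GFAP near the wild type (deviation 0.08). Within 1 log2 unit of their median lay 8 of 12 markers. The cut-off for that count was set after the result was seen, so the count decides nothing. A lower share together with induced GFAP stays open. White blood cells stay open: the 6 detected neutrophil and monocyte genes had a median deviation of 2.43 but went both ways. S100A8, S100A9 and S100A12 were over 4-fold higher, with 585, 3705 and 241 counts. VCAN was at 8.0 CPM against 21.0 and 18.9 in wild type, but it is also on the oligodendrocyte precursor list (median deviation -1.01 here). LYZ was at 4.7 CPM against 14.9 and 11.3 in wild type, and CSF3R at 4.4 against 4.2 and 8.7. The other 5 genes had at most 7 counts in any library. The myeloid receptor gene TREM1 had 8, 8 and 3 counts in the other libraries and 485 here, and PTPRC was higher as well. Of 12 lymphocyte genes 2 were detected, with a median deviation of 0.19, and CD3E, CD3D, CD3G and MS4A1 had 0 counts in this library and at most 2 in the others. The genotypes do not divide the libraries in this way, and an effect of the transgene in 1 animal only, illness and the handling of the tissue were not tested.

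Class II antigen presentation genes were higher in both transgenic libraries, in 6 of 7 genes without overlap and with a median log2 fold change of 1.46 (1.35 without transgenic library 2), while microglial markers were lower. Alleles counted differently at the polymorphic MHC cannot account for CD74, which lies outside the MHC. It was 2.08-fold higher in the lower transgenic than in the higher wild-type library. CD74 is itself 1 of the 7 genes by which the pattern was seen, so for the genes within the MHC this explanation stays open. The microglial markers had a median log2 fold change of -0.75, which argued against more microglia with unchanged marker levels. Markers can also fall within a cell, so this median cannot count cells, and more microglia with lower markers stays open. The class was singled out after it was seen to be higher in both libraries, so these libraries cannot test whether it differs by genotype. Which cells carry the transcripts, sex, age within adulthood and differences between individual animals were not tested, and no gene passed edgeR's test.

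A set of 5 genes, chosen as typical of fast-spiking cells, was lower in both transgenic libraries. These genes, SCN4B, KCNS1, SYT2, VAMP1 and NEFH, had a median log2 fold change of -1.18 (-1.11 without transgenic library 2). SYT2 was at 206 and 89.9 CPM in wild type and 47.6 and 35.3 in transgenic cortex. Which cells carry these transcripts was not tested, so the cell type is a reading and not a result. Those genes were picked for being lower in both libraries, so these libraries cannot test whether they differ by genotype. Fewer PVALB interneurons stays open. The 13 related genes not used to see the pattern had a median of -0.36 (-0.28 without transgenic library 2). Their median absolute deviation, scaled to compare with a standard deviation, was 0.30. PVALB itself was at 44.5 and 35.5 CPM in wild type and 29.6 and 25.4 CPM in transgenic cortex. The interneuron gene ERBB4 was at 90.3 and 88.6 against 107 and 114 CPM. The place in the cortex from which the pieces were taken stays open as well, since the 5 genes also differed between the wild-type libraries (median log2 ratio 0.75 of library 1 to library 2, all 5 higher in library 1), whereas the 13 related genes did so less (0.12). The labels record no more than frontal cortex, so place and genotype cannot be told apart here.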
